A study of Bos taurus with 4 samples.

How the data were processed

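Chromaffin cells of cattle received PACAP at 100 ng/ml for 6 h at 37 C, per the labels, and total RNA was hybridised to 4 arrays of mouse cDNA clones, 1 array for each of 4 biological repeats. On every array the PACAP RNA carried Cy5 and the control RNA of the same repeat number carried Cy3, per the labels. No array had the dyes swapped, so a dye preference of a probe is part of its ratio. The mouse clones were hybridised with RNA of another species, which can lower the signal of less conserved sequences.

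Each scanner table gave 37632 spots in 48 print blocks, of which 36096 held library clones, and the others were blank or came from other plates. Repeat 3 had 1152 blank spots and 1 other plate, where the other arrays had 768 blank spots and 2 other plates. Signal intensity, its local background and the spread of that background are linear values per the file headers; the image analysis program was not given in the sources used here. The deposited mean intensity already had the local background taken off and was floored near 1. This was checked from the values: total intensity over the sum of mean and background gave a median of 113.8 to 125.1 pixels per spot, whereas total intensity over the mean alone gave up to 331.7, more than the 256 pixels of the spot box. The deposited ratio of each spot is the Cy5 over the Cy3 mean divided by 1 calibration factor per array, which was 1.69, 1.97, 1.53 and 0.432 for repeats 1 to 4. A quality score from 0 to 1 and the area of each spot in pixels are given per the file headers. The deposited series table holds log2 ratios of PACAP over control. They were recomputed as the log2 ratio after the background was subtracted a second time, with a floor of 1, less the log2 of the calibration factor, and were not centred. Their scale, centring and direction were thus found from the values; the authors' reason for that second subtraction is not given in the sources used here. The medians of the deposited log2 values were 4.67, 5.51, 4.25 and -0.38 on repeats 1 to 4.

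Because the deposited means were already corrected, no further background correction was made, as the design provides for such values, in place of normexp with offset 50. Intensities were floored at 1 and log2(Cy5 / Cy3) was normalised within each array by global loess in limma 3.58.1 (R 4.3.3), with weight 0 for blank spots, other plates and spots of no area. Spots of no area were left out, and so were the spots of other plates. The files hold 0 spots with a negative value in the column of spot marks. A clone was tested where its signal exceeded 2 background SD in at least 1 channel on at least 3 of 4 arrays, and spots of 1 clone were averaged. Of 35960 library clones, 35109 were tested. Other software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

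Mouse gene symbols came from the platform annotation supplied for the series table. That table was joined to the spots by plate position, and the join was kept where the median difference from the recomputed values over the 4 arrays was under 0.1 log2 units, which held for 35695 of 35873 entries. Of those, 92.2% lay within it on all 4 arrays. All 2292 joins that could also be checked by a shared clone identifier matched. Of the library spots, 22477 had 1 symbol, 1111 had several and 12508 had none, and no gene was named from a spot with several. The clone title in the scanner table contradicts the symbol for 10 of the 106 named genes, which is said beside those that appear in the text. A gene with several probes is represented by the probe of highest mean brightness, and for genes named in the text other probes of opposite sign are mentioned.

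The 4 arrays form 1 group, and the mean log2 ratio was tested against 0 with limma's lmFit and eBayes (intercept only, 2-sided), with Benjamini-Hochberg adjustment over all probes and, for genes of 23 lists, adjusted over the list alone. The list-alone adjustment was made within each list and not across the lists. Lists were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry. The lists, the design, the rule for naming genes and most of the alternatives were fixed before the data were examined. The lists held 737 genes, of which 571 were on the array and 551 were measured. The rule names the 5 genes of smallest p in each direction where none passes, up to 4 members of each list by smallest p, and 15 genes of chromaffin cell biology; 4 of those, DBH, PNMT, GAL and STC1, were not measured. The text gives the members that stand out and summarises the others. The labels call the arrays biological repeats without saying whether the cells came from separate animals, so the spread between arrays may cover less than that between animals.

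The procedure was tested on simulated data with 35096 probes and 4 arrays. It called 2 of 67 probes changed 2-fold, 43 of 67 changed 4-fold and 65 of 66 changed 8-fold, with 0 false calls. The simulated noise was independent between probes and between arrays, and every changed probe had values on all 4 arrays. Signal shared between arrays that does not come from PACAP was not simulated. These rates and the 0 false calls may therefore not carry over to the real arrays. The number of arrays limits the precision. Alternatives covered the background correction, the within-array and between-array normalisation, the filter on dim probes, the moderation, the pairing by array, the deposited log2 ratios as a source (with loess against brightness), the probe chosen per gene, the thresholds, and leaving out each array. Alternatives added after seeing the data were normexp with offset 50, keeping spots of no area, leaving out spots of quality score 0 or under 60 pixels, the last together with normexp, averaging the clones of each gene, and an estimated correlation for the lists under median centring.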

Results

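Gene expression was measured in bovine chromaffin cells, the catecholamine-releasing cells of the adrenal medulla, after treatment with PACAP (pituitary adenylate cyclase-activating polypeptide), a neuropeptide that raises cyclic AMP. The labels give the cell type as chromaffin cells, although their tissue entry reads brain. Cells received 100 ng/ml PACAP for 6 h, and RNA from treated and control cells of the same repeat was hybridised together to 1 array of mouse cDNA clones, for 4 biological repeats. Median signal above background was 402.7, 235.5, 99.9 and 248.2 in the PACAP channel (Cy5) of repeats 1 to 4, and 306.4, 206.4, 129.4 and 548.0 in the control channel (Cy3). Of the library spots, 97.6, 98.4, 97.8 and 91.9% exceeded 2 background SD in Cy5, against 80.9, 53.0, 46.0 and 98.3% in Cy3. Blank spots exceeded it in 5.47 to 7.12% of cases in Cy5 and 9.81 to 13.3% in Cy3. Values are given as the mean log2(PACAP / control) ± SD over 4 arrays unless another n is stated, and gene names are those of the mouse clones.

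The comparison asked which transcripts differ after PACAP. Among the genes of the lists, Tac1, Crem and Scg2 had the smallest p. Tac1, the precursor of substance P, had a log2 ratio of 1.72 ± 0.33, with control signal above background on 1 of 4 arrays. Scg2, a secretory granule protein by its symbol but patched homolog by its clone title, had 1.84 ± 0.84. Its control signal was above background on 2 of 4. Both were higher on all 4 arrays. Crem, a transcription factor gene induced by cyclic AMP, had 1.44 ± 0.35, again higher on 4 of 4 arrays. No gene passed the threshold adjusted over all probes: limma called 0 of 35109, with a lowest adjusted p of 0.453, whereas 3647 probes had an unadjusted p under 0.05 (1378 higher and 2269 lower) and 1755 would by chance. With the sign of 1 or more arrays turned, this count ran from 378 to 4197. The excess over 1755 therefore does not by itself show a PACAP effect. Adjustment over the list alone was made within each list and not across the 23 lists, so it depends on list size. At a limma p of 0.00467 Slc6a3 passed among 9 genes, while Rpl29 at 0.00223 did not among 73. Adjusted over the list alone, 7 of the 551 measured genes of the 23 lists passed. With trend and robust moderation 0 did, and from the deposited log2 ratios 0.

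The genes were Tac1 (adjusted p = 0.00263), Scg2 (0.00739), Crem (0.0168), the dopamine transporter Slc6a3 (0.0421), the metalloproteinase inhibitor Timp1 (0.0470), the small GTPase Rap1b (0.0477) and the phosphodiesterase Pde3b (0.0477). Slc6a3 had a log2 ratio of 1.00 ± 0.40, Timp1 of 1.01 ± 0.25 and Rap1b of 1.05 ± 0.35, each higher on all 4 arrays. Pde3b was lower, at -2.16 ± 1.21 on 3 arrays (n = 3), from spots with a median area of 20 pixels. Control signal exceeded background on 3 of 4 arrays for Crem, Slc6a3 and Timp1, so that these ratios, like those of Tac1 and Scg2, rest in part on control spots near background and their size is uncertain. The clone titles contradict the symbols of Scg2 (patched homolog) and Rap1b (a ubiquitin-like activating enzyme subunit). With any 1 array left out, Tac1 and Scg2 still passed over the list alone, Crem passed only without repeat 4, Pde3b only without repeat 2, and Slc6a3, Timp1 and Rap1b in none of the 4. Of the settings that tested them, Rap1b passed in 11 of 21, Slc6a3 in 11 of 20, Timp1 in 10 of 20 and Pde3b in 10 of 17. Log2 ratios ranged over the settings from 0.94 to 1.92 for Tac1, 1.22 to 3.55 for Scg2, 0.98 to 2.94 for Crem. They ranged from 0.81 to 1.19 for Slc6a3, 0.63 to 1.77 for Timp1, 0.90 to 1.75 for Rap1b and -6.34 to -1.07 for Pde3b. Other genes passed over the list alone only under alternatives, among them Penk in 8 settings, Tubb3 in 5, Tgfb2 in 4, Fdft1, Cplx1 and Rpl29 in 2, and Chgb, Th, Dusp5, Homer1, Rims2 and Pcna in 1.

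**Figure D1:**
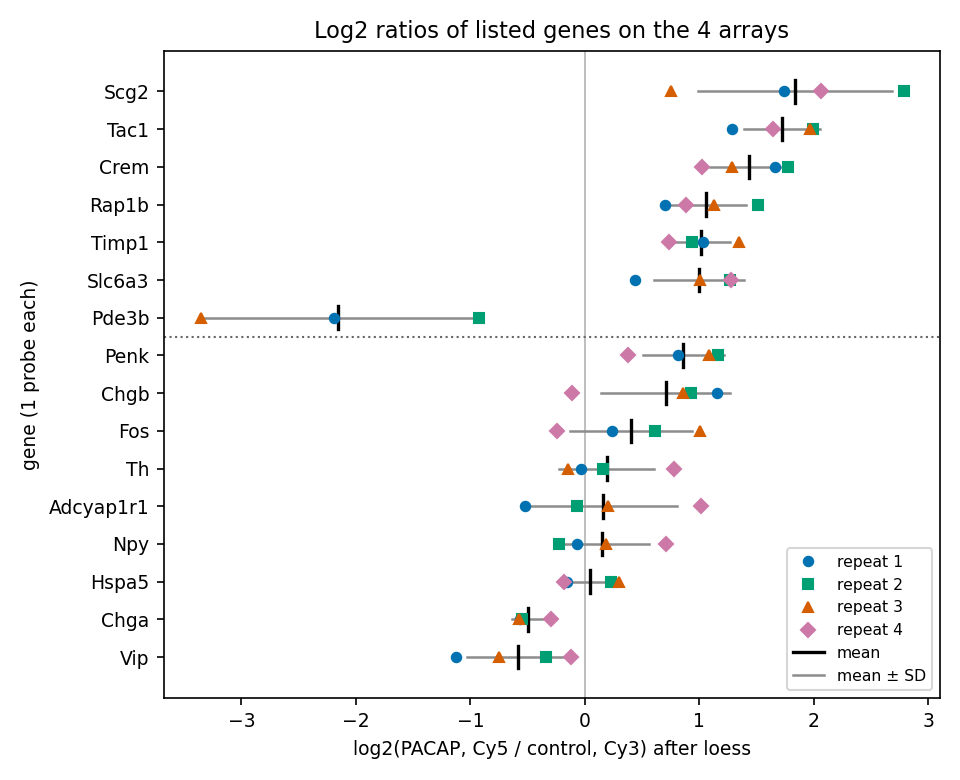
Log2(PACAP, Cy5 / control, Cy3) after loess on the x axis for genes on the y axis, 1 probe each; coloured symbols are the arrays of repeats 1 to 4, the black tick is their mean and the grey line the mean ± SD. Above the dotted line are the 7 genes past the threshold adjusted over the list alone, with Scg2 at 1.84 and Pde3b at -2.16; below it are the always-named genes that did not pass, from Penk at 0.86 to Vip at -0.58.

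Among all named genes, the smallest p on the higher side belonged to Dus1l, a tRNA dihydrouridine synthase (1.87 ± 0.39), the neuronal kinase Dclk1 (1.99 ± 0.54), Tac1, the cytokine receptor kinase Jak1 (1.62 ± 0.51) and Crem, each with an adjusted p of 0.453 and higher on all 4 arrays. Other probes were not uniform: of 4 others for Dclk1, 3 were higher and 1 lower, and of 3 for Jak1, 2 were higher and 1 lower. The other Dus1l probe was higher too, but only at 0.22. On the lower side stood Fnip1 (-2.51 ± 0.75), Armt1 (-3.93 ± 1.94), Nceh1 (-2.63 ± 0.61, n = 3), Nat8l (-2.70 ± 0.77, n = 3) and 1700028E10Rik (-1.79 ± 0.14, n = 3), also at an adjusted p of 0.453. The last 3 came from spots with median areas of 27, 16 and 49.5 pixels and had no spot on repeat 4. The sizes on the lower side depend on the processing: for the same probe, ratios ranged from -7.81 to -2.05 for Nat8l, -7.28 to -2.20 for Fnip1, -6.43 to -1.70 for Nceh1, -5.96 to -3.08 for Armt1 and -2.78 to -1.33 for 1700028E10Rik. The other Nat8l probe was higher, and took its place in 6 of 20 settings, and the Fnip1 clone carries a title that contradicts its symbol; of 4 other Fnip1 probes, 1 was higher and 3 lower. Among probes with no gene name, AI853929 (1.25) and AI843238 (1.37) were higher and C80571 (-3.32) and AW490525 (-2.29) lower, again with an adjusted p of 0.453.

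Of 23 measured genes of neuropeptides and their processing, 2 (Tac1 and Scg2) passed as higher over the list alone, 0 as lower and 21 did not pass. Penk, the enkephalin precursor, had 0.86 ± 0.35 (higher on 4 of 4 arrays; adjusted p = 0.0701 over the list alone), and the granule protein Chgb had 0.71 ± 0.56 (adjusted p = 0.210). Under median centring, which omits the loess, both passed, at 1.80 (adjusted p = 0.0168 over the list alone) and 1.65 (adjusted p = 0.0302). In that setting 20 list genes passed, against 7 in the reported analysis, so passing there does not single out these genes. Chga, the other major granule protein, had -0.50 ± 0.14, and its 2 other probes were lower too, but it had 0.64 under median centring. Vip had -0.58 ± 0.45, from a clone whose title names a DnaJ protein, and Npy had 0.15 ± 0.41, each with control signal above background on 2 of 4 arrays. The list mean was 0.18 (camera adjusted p = 0.508). In catecholamine synthesis and transport, 1 of 9 measured genes (Slc6a3) passed as higher and 8 did not; tyrosine hydroxylase, Th, the rate-limiting enzyme, had 0.19 ± 0.42, and was 1.24 under median centring, where it passed (adjusted p = 0.0304 over the list alone), and -0.05 under print-tip loess. Its list mean was 0.02, with a median of -0.03 and a downward camera test (adjusted p = 0.983).

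Among immediate early and cyclic AMP response genes, 1 of 40 (Crem) passed over the list alone and 39 did not. Dusp6, a phosphatase of ERK kinases, had 1.00 ± 0.50 (control signal above background on 2 of 4 arrays), Dusp5 had 0.65 ± 0.27 and Fos 0.40 ± 0.53, while Homer1 had -2.07 ± 1.70 (n = 3) from spots of 12 pixels and -7.76 to -0.89 over the settings. The list mean was 0.06 (camera adjusted p = 0.497). Of 32 genes of the PACAP receptor and cyclic AMP signalling, Rap1b passed as higher, Pde3b as lower and 30 did not pass. The PACAP receptor gene Adcyap1r1 had 0.15 ± 0.65, with repeat 4 at 1.02 and a range of -0.13 to 1.45 over the settings. Adenylate cyclase Adcy6 had -0.68 ± 0.31 with 1 other probe higher. This list's mean was -0.01, its median 0.07 and its camera test upward (adjusted p = 0.651). Of 26 cytokines and growth factors none passed over the list alone; Tgfb2 had 1.91 ± 1.48, higher on 4 of 4 arrays (adjusted p = 0.135 over the list alone). Repeat 3 was at 4.05, the mean was 1.19 without that repeat, and control signal exceeded background on 2 of 4 arrays. The list mean was 0.08 (camera adjusted p = 0.546). In plasminogen and matrix proteolysis, 1 of 16 (Timp1) passed and 15 did not, with a list mean of -0.004, a median of -0.03 and an upward camera test (adjusted p = 0.983).

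Ion channels and nicotinic receptors had the lowest camera p of the 23 lists: 22 of 36 measured genes were lower and 14 higher, with a mean of -0.24, but the adjusted p was 0.488, and 0.790 with an estimated correlation. Scn3b, a sodium channel subunit, had -1.61 ± 1.27 (-6.32 to -0.60 over the settings) from spots with a median area of 47.5 pixels. Chrna4, a nicotinic receptor subunit, had -0.95 ± 0.80 from spots of 68.5 pixels, with repeat 3 at -2.15 and 1 other probe higher. The purinergic receptor P2rx2 had 0.76 ± 0.48 (-0.35 to 0.91 over the settings). Of the 36, 0 passed over the list alone. In the neurite and cytoskeleton list, 0 of 31 passed: Tubb3, neuronal tubulin, had -0.98 ± 0.24 on 4 of 4 lower arrays (adjusted p = 0.107 over the list alone) and Nefl, the light neurofilament, -0.66 ± 0.13, which became 0.04 under median centring and had 1 of 4 other probes higher. That list's mean was -0.10, against a median of 0.06 (camera downward, adjusted p = 0.497). In the regulated secretion machinery 0 of 30 passed; Cplx1 had -2.36 ± 1.90 from spots of 11.5 pixels (-5.55 to -1.47 over the settings), and Rims2 had 0.69 ± 0.51, with 1 other probe lower, but -1.26 from the deposited log2 ratios (list mean -0.11, camera adjusted p = 0.508).

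Lists of metabolism, protein folding and growth held 0 genes past the threshold over the list alone in the reported analysis. Of 28 genes of the unfolded protein and amino acid response, 17 were higher, with a mean of 0.10 (camera adjusted p = 0.497). Under median centring the mean was 0.46 (adjusted p = 0.00643, but 0.883 with an estimated correlation) and 5 genes passed over the list alone. Hspa5, the endoplasmic reticulum chaperone, had 0.05 ± 0.25. Heat shock proteins had a mean of 0.18 over 17 genes (adjusted p = 0.497), with Hspe1 at 0.98 ± 1.18 (control signal above background on 2 of 4 arrays). Under median centring the mean was 0.68 (adjusted p = 0.00576, but 0.883 with an estimated correlation) and 4 genes passed over the list alone. For cholesterol synthesis and uptake the mean over 19 genes was -0.01 (adjusted p = 0.759), with Fdft1, squalene synthase, at -0.77 ± 0.46 and Mvk, mevalonate kinase, at 0.90 ± 0.84 (control signal above background on 2 of 4 arrays). Glycolysis had a mean of -0.05 over 17 genes (adjusted p = 0.546) and oxidative phosphorylation 0.04 over 46 (adjusted p = 0.774), with Ndufa2 at 0.75 ± 0.18 (control signal above background on 1 of 4 arrays). In the cell cycle list of 34 genes the mean was -0.10 (adjusted p = 0.497), with Pcna at 0.82 ± 0.48 and the kinase Ttk at -1.04 ± 0.61. That list's mean was -0.38 on repeat 2, against -0.09 to 0.04 on the other arrays. Cell survival and death had a mean of -0.03 over 14 genes (adjusted p = 0.625). The 73 ribosomal protein genes had a mean of -0.07 (adjusted p = 0.508), with Rpl29 at -1.13 ± 0.40 (1 of 2 other probes higher), but the list mean was 0.54 under median centring (adjusted p = 4.51e-04, but 0.883 with an estimated correlation of 0.745).

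Markers of other cell types that an adrenal preparation could hold gave 0 genes past the threshold over the list alone. The mean was -0.14 for 9 adrenal cortex genes (camera adjusted p = 0.508), 0.15 for 16 fibroblast and matrix genes (adjusted p = 0.546; 0.56 under median centring, where the adjusted p = 0.00617 at the preset correlation and 0.883 with an estimated one), 0.13 for 11 endothelial genes (adjusted p = 0.508) and -0.39 for 3 erythrocyte genes (adjusted p = 0.497). For 12 leukocyte genes it was 0.10, with a downward camera test (adjusted p = 0.983), and for 9 Schwann and sustentacular genes -0.06, with a median of 0.09 (adjusted p = 0.903). On single arrays the adrenal cortex mean lay between -0.51 (repeat 3) and 0.10 (repeat 4), and the ribosomal mean between -0.55 (repeat 4) and 0.35 (repeat 1). Camera called 0 of 23 lists (4 under median centring, but 0 there with an estimated correlation), with an adjusted p of 0.790 or more with an estimated correlation, and 1 list had an unadjusted p under 0.05. Fry, which tests whether a list's genes move one way on balance, gave a lowest adjusted p of 0.215, and 0.0687 for changes in either direction. Under median centring, print-tip loess, scaling between arrays and the deposited log2 ratios, the list means kept their sign for neuropeptides, ion channels, heat shock proteins, fibroblast, adrenal cortex, cell cycle, cholesterol and Schwann genes, and turned under at least 1 of these for each other list. Left-out arrays are not covered by this. The Schwann mean was -0.50 on repeat 3 and 0.01 to 0.16 on the other arrays, so its sign rests on repeat 3. The fibroblast mean was 0.47 on repeat 3 and -0.06 to 0.11 on the other arrays.

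**Figure D2:**
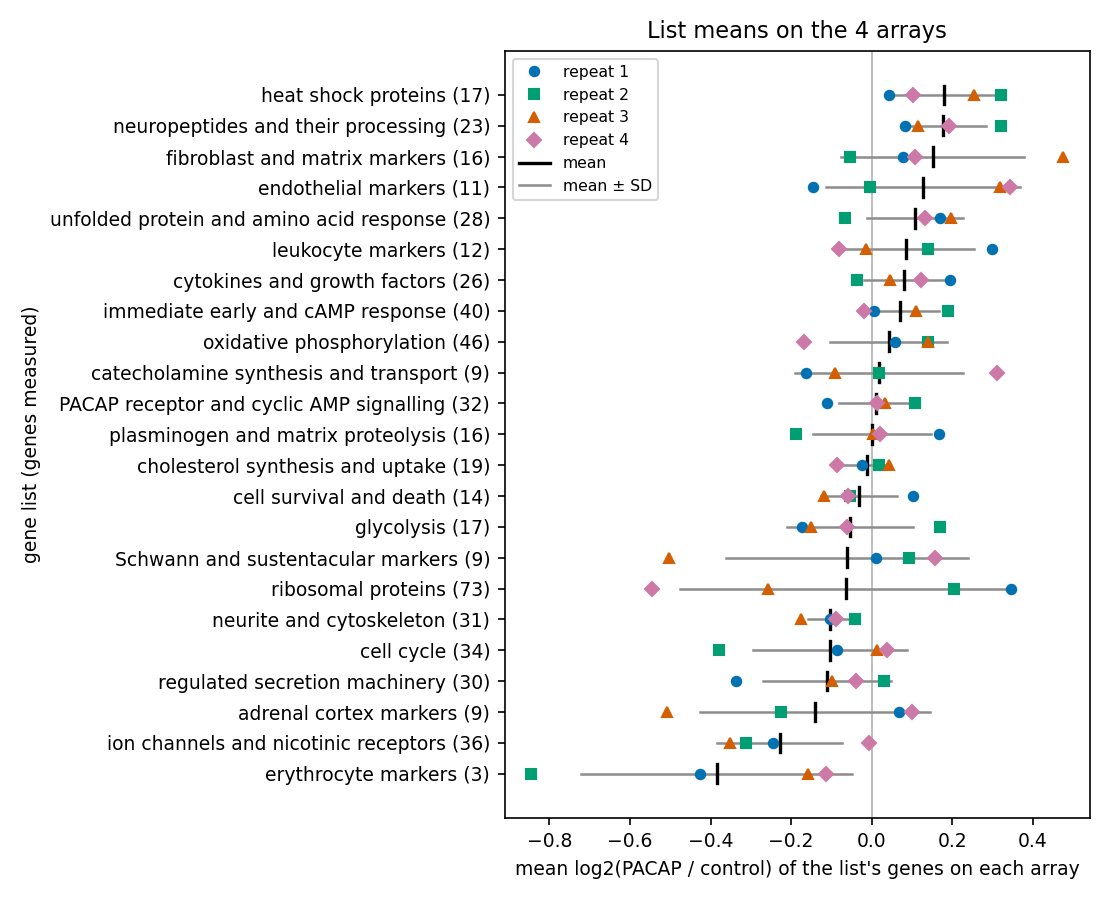
Mean log2(PACAP / control) of the measured genes of each list on the x axis, with the lists and their numbers of genes on the y axis; coloured symbols are the arrays of repeats 1 to 4, the black tick is the mean over arrays and the grey line that mean ± SD. Ribosomal proteins run from -0.55 on repeat 4 to 0.35 on repeat 1, and ion channels lie between -0.35 and -0.01.

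The log2 ratios correlated more among repeats 1 to 3 than with repeat 4. Across probes, which are not independent replicates, Pearson's r of the log2 ratios was 0.232, 0.296 and 0.385 for the pairs among repeats 1 to 3, with a mean of 0.304. For repeat 4 with repeats 1, 2 and 3 it was -0.016, -0.128 and -0.008, with a mean of -0.051. In the brightest of 5 equal groups of probes the means were 0.341 and 0.182. Of 11375 named genes with values on all 4 arrays, 2256 had the same sign on each. Independent signs would give 1 in 8, but repeats 1 to 3 correlated with one another. The count therefore does not show that repeat 4 shared their direction. The median SD over arrays was 0.55.

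**Figure D3:**
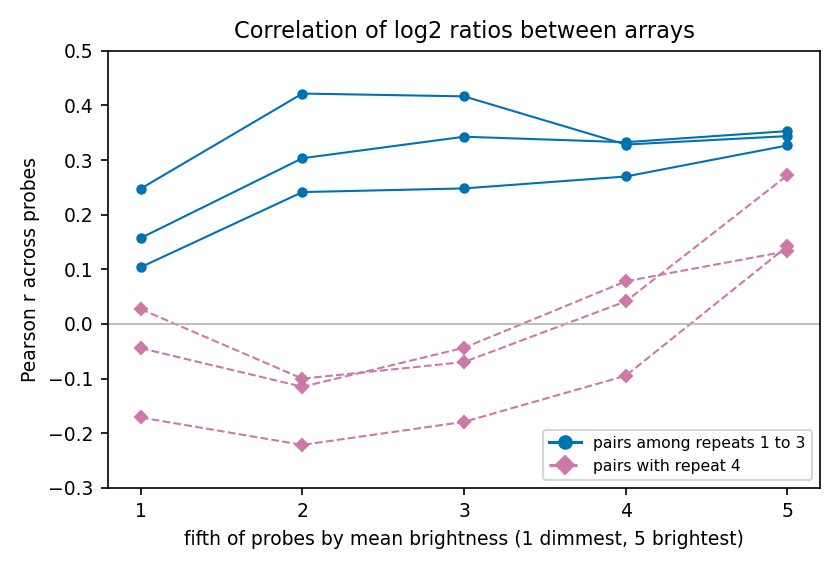
Pearson's r of log2 ratios between pairs of arrays on the y axis for 5 equal groups of probes by mean brightness on the x axis, from dimmest to brightest; solid lines with circles are pairs among repeats 1 to 3 and dashed lines with diamonds are pairs with repeat 4. In the brightest group the 3 pairs with repeat 4 lie between 0.133 and 0.272, and those among repeats 1 to 3 between 0.327 and 0.353.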

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

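The tests of repeat 4 in this part were chosen only after the result was seen. On 4 arrays, 130 values were examined for an array far from the others, a check that chance meets in about 1 of 20 groups, and 4 stood apart. The complement gene C1qc had a log2 ratio of 2.18 on repeat 3, against -0.07 to 0.16 on the others. Chga had -0.30 on repeat 4, against -0.58 to -0.55. Chrna4 had -2.15 on repeat 3, against -0.62 to -0.44. The share of library spots above 2 background SD in Cy5 was 91.9% on repeat 4, against 97.6 to 98.4%.

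The log2 ratios of repeat 4 did not follow those of repeats 1 to 3. Dim spots as the whole cause are argued against, because in the brightest of 5 equal groups of probes the mean r of repeat 4 with the others was 0.182, still below the 0.341 among repeats 1 to 3 (95% interval of the gap 0.121 to 0.194, block bootstrap of 1000 draws). Small spots as the whole cause are argued against too: without spots under 60 pixels the mean r was 0.0311, against 0.215 (gap 0.127 to 0.240). The block bootstrap intervals given here and further below do not cover the spread between arrays, and repeat 4 is only 1 array. An exchange of PACAP and control RNA on repeat 4 could turn correlations below 0, and the lower 95% bound among the brightest probes was 0.146 (upper bound 0.222), but a dye preference of single probes adds a positive correlation on arrays of one orientation, so the explanations cannot be told apart; with repeat 4 turned, limma gave 0 probes past the threshold and 4197 at an unadjusted p under 0.05 (3647 as labelled), but 1 gene over the list alone (7 as labelled) and 0 genes with several clones (2 as labelled). A difference between the cell preparations stays open and was not tested. Repeat 4 also differed in channel balance. Its calibration factor was 0.432, against 1.53 to 1.97 on the others. In Cy3, 98.3% of its library spots exceeded 2 background SD, against 46.0 to 80.9%. Whether this bears on the correlations was not tested.

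Signal also appeared on a plate outside the clone libraries, with 130 titled spots, which was used in no comparison. Above 2 background SD were 38.0% of its spots in Cy5 and 40.9% in Cy3 on repeat 1, 40.6 and 40.9% on repeat 2, 38.3 and 41.1% on repeat 3, and 44.5 and 55.5% on repeat 4. Blank spots of the same arrays exceeded it in 5.47 to 7.12% of cases in Cy5 and 9.81 to 13.3% in Cy3.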

How the results depend on the processing

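The settings with normexp at offset 50, spots of no area, spots of quality score 0 and spots under 60 pixels, and median centring with an estimated correlation, were chosen after seeing the data. Every setting gave 0 probes past the threshold in limma (3647 at an unadjusted p under 0.05 in the reported analysis), as did an adjusted p under 0.1 or a further 2-fold limit, with 2 exceptions. No background correction gave 15 probes (5 higher, among them Dclk1, Dus1l, Jak1 and Ddx3x, and 10 lower, among them Armt1), and leaving out spots under 60 pixels together with normexp at offset 50 gave 1 (0 higher, 1 lower, Fnip1 at -2.57, adjusted p 0.0452). Named genes kept their direction and side of the threshold in 1962 values, turned without passing in 64 and passed in 6; 65 of 106 kept their sign in every setting run. List means did so in 406, turned in 48, passed in 3 and reversed in 1. The exceptions that passed all came from median centring without loess, with 4 lists: unfolded protein response 0.46, heat shock 0.68, fibroblast 0.56, and ribosomal proteins, which reversed to 0.54 (adjusted p 4.5e-04 at the preset correlation); with an estimated correlation 0 lists passed there (lowest adjusted p 0.883). Over the list alone, 7 genes passed in the reported analysis, 18 with no background correction, 20 under median centring, 0 with trend and robust moderation, 0 from the deposited log2 ratios, 4 with spots of no area kept, 11 without spots under 60 pixels with normexp at offset 50, and 2 to 6 with 1 array left out. Each array pairs treated and control RNA of 1 repeat; with no replicate block, 0 probes and 4 list genes passed. Tac1 and Scg2 passed over the list alone in 18 of 21 settings and Crem in 15. Tac1, Scg2 and Crem were not tested where both channels had to exceed background on all 4 arrays, and did not pass with trend and robust moderation or the deposited log2 ratios, whose median over probes was -0.17 after loess. Fewer probes enter the filter on both channels; for the other changes the cause was not tested. No setting was run with negative spot marks left out, of which there were 0, or with foreground medians, since means were used. Signal over background limits the control channel on repeats 1 to 3, down to 46.0% of spots above 2 background SD on repeat 3, but not on repeat 4 (98.3%, against 91.9% for PACAP).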

Other observations

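Averaging the clones of each gene, the tests of small spots, the sign patterns, the test of a second background subtraction and that of PACAP signal before calibration were chosen only after the result was seen. With 5939 genes of several clones averaged, 2 passed limma's adjusted threshold, both higher on all 4 arrays. Tac1 had a log2 ratio of 2.26 ± 0.62 (n = 4 arrays, adjusted p = 0.0249) from clones at 2.79 and 1.72, the first of which carries a calcium channel title; control signal exceeded background on 1 of 4 arrays for each clone. Crem had 1.54 ± 0.37 (adjusted p = 0.0455) from clones at 1.64 and 1.44, with control signal above background on 1 and 3 of 4 arrays. The sizes are therefore uncertain. Among those that did not pass were Bzw2 at 1.16 ± 0.16 over 3 clones (adjusted p = 0.0994), the membrane protein Tm4sf1 at 1.29 ± 0.46 (0.123) and the RNA helicase Ddx3x at 0.96 ± 0.40, with all 7 clones higher (0.249). The titles of the Ddx3x clones include another gene, fibroblast growth factor inducible 14. On the lower side, Fdft1 had -0.97 ± 0.41 and Rpl23a -0.80 ± 0.35, with all 4 Rpl23a clones lower (adjusted p = 0.249 and 0.305). Without repeat 3 or repeat 4 Tac1 was at 1.99 and 2.45 and passed; without repeat 1 or repeat 2 it did not pass, while Crem failed with any 1 array left out. Over the other settings the number of such genes ran from 0 (median centring, trend and robust moderation, no replicate block, deposited log2 ratios) to 11 (spots of quality score 0 left out), and where both channels had to exceed background neither Tac1 nor Crem was tested. With normexp at offset 0, print-tip loess, no filter on dim probes or spots of no area kept, Tac1 passed and Crem did not. Over the 8 sign patterns of the 4 arrays, 1 gave as many genes as the 2 observed, with 0 in the highest other; for single probes all 8 gave as many as the observed 0. With 8 patterns no share can be under 1 in 8, so they are too few to decide.

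Different clones of a gene gave weakly related ratios. Over 5664 genes, the 4-array means of a pair of clones correlated at 0.0943, against at most 0.0448 in 100 pairings of clones of different genes. A sequence-specific signal shared by clones may account for this, which stays open: between repeats 1 to 3 and repeat 4, clones of a gene correlated at 0.0211, inside the 0.0333 of other pairings, while within repeat 4 they correlated at 0.131 (other pairings at most 0.0300) and in the means of repeats 1 to 3 at 0.0760 (at most 0.0524). Whether such a signal follows PACAP or dye cannot be told apart, since the dyes were not swapped.

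More probes were lower than higher at an unadjusted p under 0.05, by 2269 to 1378. Small spots may account for part of the lower ones: 48.4% of them had a median area under 60 pixels, against 8.88% of all probes (95% interval of the difference 35.6 to 43.9 percentage points) and 0.145% of the higher ones. As the whole cause small spots stay open, because without them the ratio of lower to higher probes was 1.19, with an interval of 0.805 to 1.70, against 1.65 with them. No biological explanation was tested.

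The deposited log2 ratios had medians of 4.67, 5.51 and 4.25 on repeats 1 to 3. More PACAP than control signal as the cause is argued against: with the background subtracted once and no calibration factor, the highest median on those arrays was 0.56, against a lowest deposited median of 4.86 with the factor added back. With the factor applied the highest was -0.19, which decides nothing because the factor can centre the ratios. A second subtraction of the background may be the cause. Values recomputed that way lay within 0.1 log2 units of the deposited ones, by the median over arrays, for 35695 of 35873 entries. Over those entries, kept for that closeness, recomputed and deposited values correlated at 0.999775 or more on each array. The correlation was therefore partly set by the choice of entries. The second subtraction brought the control channel to the floor on 58.2, 83.1 and 81.5% of library spots of repeats 1 to 3, against 7.46% on repeat 4. No biological explanation was tested.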
